A study of Homo sapiens with 18 samples.

How the data were processed

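Total RNA had been taken with an RNeasy Plus Mini kit and sequenced as stranded, polyadenylated RNA (TruSeq Stranded mRNA), per the labels' protocols. The cells were cultured in triplicate with 0.1% DMSO as the vehicle or 500 ng/ml doxycycline in medium with 10% serum. Reads had been aligned to GRCh38 with STAR, and DESeq2 had been used, per the submitters' processing notes, which give no versions. The authors deposited 1 table of TPM, a unit in which every column adds up to 1000000, per cell line, with 6 columns each and 25673 gene names for RKO, 19909 for COLO 201 and 19977 for H1975. Of these, 7344, 3535 and 3023 were 0 in every column. The sums were 1000000 in each column, and no 2 columns of a table held identical values.

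All 18 sample records carry the same agent label, so samples were grouped by cell line and the arm was read from the authors' column headings, by a rule fixed before the data were examined. In COLO 201 and H1975 the headings set a minus sign, written as a point, against plus. In RKO they set DOX with no sign against DOX with plus. The columns headed DOX alone were read as vehicle because the protocol names only DMSO and doxycycline. The rule asked for headings that name the arm, and DOX alone does not name the vehicle, so the RKO reading departs from it. MUC1 in each column served as the check of the headings. The column numbers 1 to 3 could not be tied to single sample titles. No column of a control hairpin with doxycycline was available here, so effects of the hairpin and of doxycycline itself were not separated.

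The tables follow different gene lists. In RKO small noncoding RNA genes took 67.5% to 78.5% of TPM and no mitochondrially encoded gene was listed, while mitochondrially encoded genes took 16.9% to 23.0% in COLO 201 and 16.1% to 22.5% in H1975. The 10 most abundant genes took 67.5% to 78.4% in RKO, 18.2% to 23.2% in COLO 201 and 15.2% to 21.6% in H1975. In COLO 201, 28 entries named as dates, at most 0.0684% of TPM, were left out. Older gene symbols were matched to current ones through RefSeq gene synonyms (1102, 1330 and 1355 entries), and GENCODE release 29 gave positions and 3′ UTRs. Symbols of the tables are used within a line and current symbols between lines. WARS is WARS1, FAM49B is CYRIB, C2ORF54 is MAB21L4, PVRL2 is NECTIN2, IL8 is CXCL8, SDPR is CAVIN2, METTL7A is TMT1A and ATP5G1 is ATP5MC1. TPM keep no read totals, so the absolute depth per sample is unknown. The most common ratio of low values between columns, shared by 14.9% to 21.2% of the genes used, put the relative depth of the columns within 2.11-fold in RKO, 2.30-fold in COLO 201 and 2.22-fold in H1975.

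Genes with a mean TPM of at least 1 over the 6 columns were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a trend in the prior variance, two-sided, and Benjamini-Hochberg adjustment over the genes tested in a line. Calls are adjusted p under 0.05. The 30 gene lists were fixed before the data were examined: NKG2D ligands, ligand shedding proteins, exosome release, exosome biogenesis, tetraspanins, other natural killer and death receptor ligands, immune checkpoint genes, DNA methylation enzymes, Polycomb and SWI/SNF complexes, interferon-stimulated genes, MHC class I, NF-kB targets, mesenchymal genes, epithelial junctions, stemness factors, cell cycle, MYC targets and ribosome biogenesis, p53 targets, the integrated stress response, the unfolded protein response, mitochondrially encoded and nuclear OXPHOS genes, cholesterol synthesis, hypoxia and glycolysis, mucins, and colon, lung, fibroblast and endothelial, and leukocyte and erythroid markers. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a line, and again with an estimated correlation and with fry. MUC1 was also tested with an exact two-sided permutation test.

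Differences between lines were tested in a joint limma fit with a mean per line and arm, as contrasts of the differences within tables. Overlaps used one-sided Fisher's exact tests. Genes were named by a rule fixed before the data were examined: the 9 study genes, the 8 rising and 8 falling genes with the largest change in each line whose arms did not overlap, up to 4 members of a list with the smallest adjusted p, the 8 rising and 8 falling genes called in every line with the largest smallest change, and 3 genes with opposite calls per pair of lines. Every 7-base word was counted in the 3′ UTRs of the genes lower in every line, against genes of like 3′ UTR length, with a normal approximation of the count and Bonferroni adjustment over 12649 words. The minimum expected count of 5, the random gene sets set beside it and the removal of MUC1 from the set were chosen after results had been seen.

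The alternatives were pseudocounts of 0.1 and 5, no minimum TPM and a minimum of 5, columns rescaled by the median ratio to the geometric mean, mitochondrially encoded genes removed, no trend, the column number as a block, each column left out, and a minimum change of 2-fold. Removal of small noncoding RNA genes and removal of RKO vehicle column 1 together with rescaling were added later, as were the study genes between lines under rescaling or without that column, the mucins without MUC1, and the word counts without the genes in which the word was found. Same-number columns were paired by no label, and their correlations after removal of the arm means were 0.29, 0.27 and -0.01 in RKO, -0.05, 0.15 and 0.28 in COLO 201 and 0.16, -0.42 and -0.35 in H1975, so the fits took no pairs. On simulated data with 200 changed genes per line, 2-fold changes were recovered for 28.4% of genes in RKO, 98.5% in COLO 201 and 92.5% in H1975, and 1.5-fold changes for 0%, 79.1% and 70.2%, with 3.57%, 3.67% and 1.71% of calls false. The simulated spread was drawn gene by gene from a normal distribution with the widest spreads capped, without shifts shared across a column. The recovered and false shares therefore do not cover such shifts or genes of wider spread. Nor do they cover the larger numbers of genes called in the real data. The other tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.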

Results

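Messenger RNA was sequenced in 3 human cancer cell lines that carried a doxycycline-inducible short hairpin RNA against MUC1, which encodes a transmembrane mucin. RKO and COLO 201 are colon cancer lines and H1975 is a lung cancer line. The series is about the C-terminal subunit of MUC1, the stress ligands MICA and MICB, which are recognised by the NKG2D receptor of natural killer cells, and the release of exosomes. Each line had 6 samples, given in the authors' 3 tables of TPM, a unit in which every column adds up to 1000000. The headings mark 3 columns per line as with doxycycline, and the other 3 were read as vehicle. In RKO these 3 are headed DOX and carry no minus sign, and that reading was inferred from the protocol. The protocol gives 500 ng/ml doxycycline and 0.1% DMSO as the vehicle. Between 14935 and 16935 genes were above 0 per column in RKO, 14712 to 15217 in COLO 201 and 15235 to 16083 in H1975. Every change given here is doxycycline against vehicle on the log2(TPM + 1) scale, with its standard error from limma, and n = 3 per arm. The tables were treated as normalized separately, so levels were not compared between lines, apart from those of RKO vehicle column 1 in the last part.

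MUC1 (GRCh38 chromosome 1, 155185824 to 155192916, minus strand), the gene targeted by the hairpin, was lower in every doxycycline column than in every vehicle column of its line. In COLO 201 it fell from 13.9 ± 0.940 (SD, n = 3) to 1.78 ± 0.250 TPM, a log2 change of -2.43 ± 0.08 (limma adjusted p = 3.5e-10). In H1975 it fell from 97.5 ± 9.98 to 8.01 ± 1.35 TPM, a log2 change of -3.46 ± 0.10 (limma adjusted p = 4.1e-11). In RKO the vehicle columns stood at 15.2, 1.24 and 1.03 TPM and the doxycycline columns at 0.108, 0.105 and 0.204 TPM, a log2 change of -1.88 ± 0.43 (limma adjusted p = 0.0027). The mean under doxycycline was 2.38% of the vehicle mean in RKO, 12.8% in COLO 201 and 8.22% in H1975. Without vehicle column 1 the RKO value was 12.2%, from 1.13 to 0.139 TPM. The exact two-sided permutation p for MUC1 was 0.1 in each line, which is the smallest that 3 against 3 columns can give. The RKO call rested on vehicle column 1: without it MUC1 fell below the minimum of 1 TPM and was not tested, and after rescaling of the columns by their median ratio the change was -1.77 (limma adjusted p = 0.15).

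**Figure D1:**
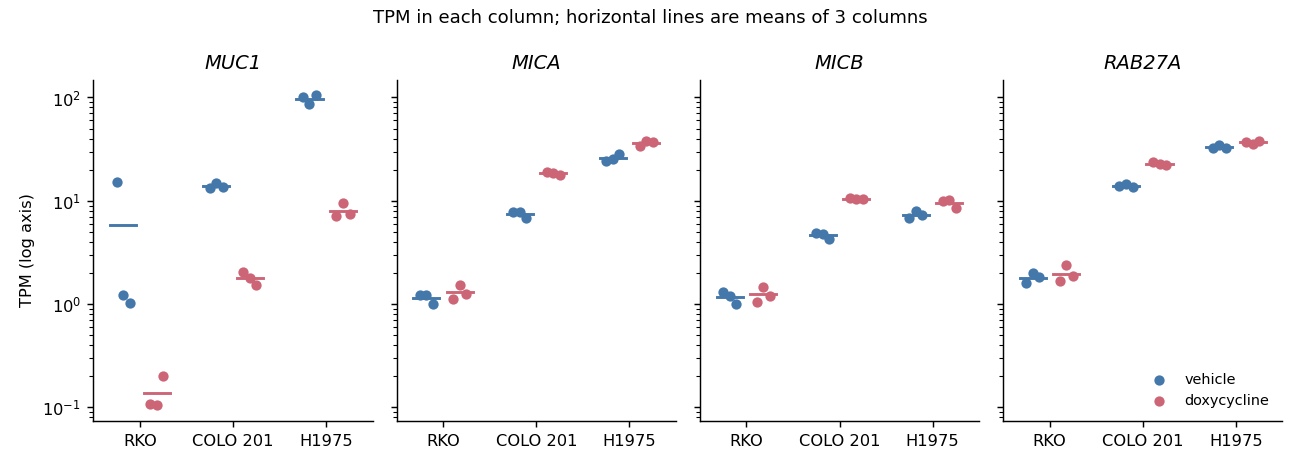
TPM on a log axis of MUC1, MICA, MICB and RAB27A in each of the 3 vehicle (blue) and 3 doxycycline (pink) columns of RKO, COLO 201 and H1975, with horizontal lines at the mean of 3. MUC1 was lower in every doxycycline column of its line, MICA and MICB were higher in COLO 201 (18.5 against 7.47 TPM and 10.5 against 4.65 TPM) and H1975, and RKO vehicle column 1 held 15.2 TPM of MUC1.

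MICA (chromosome 6, 31399784 to 31415315, plus strand) and MICB (chromosome 6, 31494881 to 31511124, plus strand), cell surface ligands of NKG2D, rose in COLO 201 and H1975. In COLO 201 MICA rose from 7.47 ± 0.537 to 18.5 ± 0.538 TPM (log2 change 1.21 ± 0.06, limma adjusted p = 1.2e-08) and MICB from 4.65 ± 0.357 to 10.5 ± 0.201 TPM (1.03 ± 0.06, limma adjusted p = 6.8e-08). In H1975 MICA rose from 26.0 ± 2.02 to 36.4 ± 2.24 TPM (0.47 ± 0.08, limma adjusted p = 3.8e-04) and MICB from 7.36 ± 0.543 to 9.61 ± 0.922 TPM (0.34 ± 0.09, limma adjusted p = 0.0074, and 0.052 without vehicle column 1). In RKO both were near 1 TPM in either arm and neither passed the test (MICA 0.10 ± 0.22 and MICB 0.05 ± 0.23, limma adjusted p = 0.78 and 0.90). With vehicle column 1 out and the columns rescaled by their median ratio, they were 0.29 and 0.26 and passed (limma adjusted p = 9.1e-04 and 0.0020). RAB27A (chromosome 15, 55202966 to 55319113, minus strand), a small GTPase of vesicle docking and secretion, rose in COLO 201 from 14.01 ± 0.377 to 22.9 ± 0.677 TPM (0.67 ± 0.05, limma adjusted p = 2.6e-07). It did not pass in H1975 (0.14 ± 0.07, limma adjusted p = 0.11) or RKO (0.08 ± 0.20, limma adjusted p = 0.81), where it was 0.23 (limma adjusted p = 0.0044) with vehicle column 1 out and rescaled.

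The other study genes moved differently from line to line. DNMT1, the maintenance DNA methyltransferase, fell in RKO from 39.7 ± 3.68 to 18.7 ± 3.02 TPM (-1.06 ± 0.21, limma adjusted p = 9.9e-04). That fall was -0.77 after rescaling (limma adjusted p = 9.2e-04) and -0.82 with small noncoding RNA genes removed (limma adjusted p = 0.0013). DNMT3A, a de novo DNA methyltransferase, fell in COLO 201 (-0.25 ± 0.05, limma adjusted p = 0.0018) and H1975 (-0.68 ± 0.08, limma adjusted p = 2.0e-05). DNMT3A and DNMT3B both hold in their 3′ UTR the 7-base word described with the shared genes, and DNMT3B did not pass in any line (limma adjusted p = 0.24, 0.64 and 0.11 in RKO, COLO 201 and H1975). PDIA6, a disulfide isomerase, fell by 0.11 ± 0.04 in COLO 201 (limma adjusted p = 0.032) and rose by 0.20 ± 0.07 in H1975 (limma adjusted p = 0.035). Its value of -0.53 ± 0.23 in RKO did not pass (limma adjusted p = 0.096). Both PDIA6 calls were lost on leaving out any of 4 single columns (limma adjusted p = 0.055 to 0.14 in COLO 201 and 0.073 to 0.14 in H1975) and without the trend (0.070 and 0.055). The passing values of DNMT1 (0.12) and EZH2 (0.11), the Polycomb methyltransferase, in COLO 201 had limma adjusted p = 0.030 and 0.034, and turned to -0.01 and -0.02 after rescaling.

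The NKG2D ligands did not move as a group. Of the 7 tested in COLO 201, MICA, MICB, ULBP3 (1.17) and RAET1L (1.52) rose and RAET1E (-1.03), ULBP1 (-0.29) and ULBP2 (-0.21) fell, the same 4 and 3 when adjusted over the list alone (camera adjusted p = 0.71). In H1975 MICA and MICB rose and the other 5 fell, among them RAET1L (-0.70), RAET1E (-0.40) and ULBP1 (-0.32), the same counts when adjusted over the list alone (camera adjusted p = 0.22). In RKO 4 were tested, too few for camera, and 1 fell in limma, ULBP2 (-0.65, limma adjusted p = 0.024). Without doxycycline column 1 it did not pass (limma adjusted p = 0.23), nor without vehicle column 2 (0.18) or doxycycline column 3 (0.084).

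The lists of exosome machinery were not called as groups in any line. Release GTPases, tethers and SNAREs had 0 higher and 1 lower of 21 in RKO (camera adjusted p = 0.30), 8 and 3 of 21 in COLO 201 (0.81) and 6 and 2 of 23 in H1975 (0.75). The counts were 0 and 1, 8 and 3, and 5 and 1 when adjusted over the list alone. ESCRT and lipid biogenesis genes had 1 and 2 of 27 in RKO (camera adjusted p = 0.12), 14 and 2 in COLO 201 (0.71) and 9 and 3 in H1975 (0.61). They were 1 and 0, 14 and 2, and 10 and 3 when adjusted over the list alone. After rescaling the COLO 201 split was 7 and 8. FLOT1, a lipid raft scaffold, rose in COLO 201 (0.88 ± 0.05). SDCBP, the syntenin adaptor of exosome formation, rose in COLO 201 (0.47 ± 0.05) and H1975 (0.38 ± 0.08). The tetraspanin CD63, a marker of exosomes, rose in both lines (0.28 ± 0.04 and 0.45 ± 0.07), and CD9 rose in COLO 201 (0.50 ± 0.04). After rescaling the CD63 change in COLO 201 was 0.16 (limma adjusted p = 0.025). SDC4 (-0.42 ± 0.04, limma adjusted p = 9.0e-07), STX1A (-0.36 ± 0.05, limma adjusted p = 1.1e-04) and CD82 (-0.26 ± 0.04, limma adjusted p = 2.5e-04) fell in COLO 201. The tetraspanin list as a whole had 0 higher and 1 lower of 7 in RKO, 6 and 1 of 8 in COLO 201 and 1 and 2 of 8 in H1975, the same counts when adjusted over the list alone (camera adjusted p = 0.69, 0.71 and 0.22). TSPAN8 fell in H1975 (-1.03 ± 0.12).

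In RKO, genes of DNA replication and cell division fell. Of 42 genes of S and G2/M phases, 0 rose and 40 fell, 41 when adjusted over the list alone, with a median log2 change of -1.11 (camera adjusted p = 2.1e-23, adjusted p = 0.89 with an estimated correlation). The replicative helicase subunits MCM5 and MCM3 fell from 24.0 ± 3.50 to 6.44 ± 1.21 TPM (-1.75 ± 0.20, limma adjusted p = 1.3e-06) and from 37.5 ± 3.66 to 12.1 ± 1.66 TPM (-1.56 ± 0.21, limma adjusted p = 6.8e-06). The transcription factor E2F1 fell by 1.55 ± 0.18 (limma adjusted p = 1.7e-06) and GINS2, a partner of the helicase, fell by 1.76 ± 0.22 (limma adjusted p = 3.5e-06). The members that did not pass were CCNE1 (0.04 ± 0.20) and AURKB (-0.59 ± 0.22). After rescaling, 1 of the 42 was higher and 35 were lower (camera adjusted p = 1.2e-17).

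Camera also called p53 targets and epithelial junction genes in RKO, as higher relative to other genes. Of 10 splits of the RKO columns, the real one included, 9 called at least as many lists. The number of lists called thus does not set the real split apart. Of 24 p53 targets, 6 rose and 1 fell (7 and 2 when adjusted over the list alone), with a median of 0.13 (camera adjusted p = 3.5e-07, adjusted p = 0.89 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 1.03 ± 0.24 (limma adjusted p = 0.0028), GDF15, a stress-induced cytokine, by 0.84 ± 0.22 (limma adjusted p = 0.0070). CCNG1 fell by 0.84 ± 0.23 (limma adjusted p = 0.011). Of 10 epithelial junction genes, 3 rose and 0 fell (4 and 0 when adjusted over the list alone), with a median of 0.46 (camera adjusted p = 7.0e-09, adjusted p = 0.89 with an estimated correlation). The desmosomal PKP3 rose by 1.04 ± 0.19 (limma adjusted p = 4.1e-04), DSP by 0.66 ± 0.20 (limma adjusted p = 0.021) and KRT8 by 0.61 ± 0.21 (limma adjusted p = 0.040). Without vehicle column 1, limma called 1 of the 10 higher and DSP (adjusted p = 0.089) and KRT8 (adjusted p = 0.25) did not pass. With the columns also rescaled, DSP was 0.69 (limma adjusted p = 1.9e-06) and KRT8 0.66 (7.8e-06), and rescaled with all columns they were 0.88 (0.011) and 0.87 (0.017).

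Of 17 subunits of SWI/SNF chromatin remodelling complexes in RKO, 0 rose and 8 fell (12 when adjusted over the list alone), with a median of -0.54 (camera adjusted p = 0.022, adjusted p = 0.89 with an estimated correlation). PBRM1 fell by 0.88 ± 0.19 (limma adjusted p = 0.0017), SMARCD1 by 0.75 ± 0.21 (limma adjusted p = 0.013) and SMARCB1 by 0.68 ± 0.20 (limma adjusted p = 0.017). Of the 8 that fell, 6 hold the 7-base word described with the shared genes, against 1.08 for tested genes of like 3′ UTR length. The list is rich in the word whether or not members fell, with 8 of 17 against 2.46. In COLO 201 9 of 17 members rose, and 2 of the 5 that fell hold the word. The count in RKO thus does not tie the fall to the word. The list was not called without vehicle column 1 (camera adjusted p = 0.092), vehicle column 2 (0.15), vehicle column 3 (0.099) or doxycycline column 3 (0.057). SMARCD1 and SMARCB1 did not pass without vehicle column 2 (limma adjusted p = 0.082 and 0.063), doxycycline column 1 (0.085 and 0.098) or doxycycline column 3 (0.082 and 0.10).

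The genes that rose most in RKO were SPINK1 (2.01 ± 0.23), a secreted trypsin inhibitor listed at 0.0888 ± 0.154 TPM in vehicle and 3.39 ± 0.724 TPM in doxycycline, and ZNF165 (1.98 ± 0.19). Next were SUN3 (1.91 ± 0.23), TRIB3 (1.73 ± 0.24), a pseudokinase induced by stress, PRSS22 (1.69 ± 0.22), the metallothionein MT1X (1.58 ± 0.21), which rose from 481 ± 124 to 1411 ± 149.6 TPM, LCE1F (1.54 ± 0.24) and LOC100126784 (1.51 ± 0.20). Those that fell most were the intermediate filament gene VIM (-2.90 ± 0.86), the actin-binding TMSB4X (-2.60 ± 0.39), the caveolar coat gene CAV1 (-2.47 ± 0.55) and the histone genes HIST1H2AB (-2.51 ± 0.24), HIST3H2BB (-2.25 ± 0.28), HIST1H3C (-2.25 ± 0.78), HIST1H3J (-2.19 ± 0.25) and HIST1H4D (-2.15 ± 0.26). All 16 passed limma, with adjusted p from 1.8e-07 to 0.044. Histone genes belong to multigene families that share reads, so their single values are uncertain. How fully libraries of polyadenylated RNA capture histone messages was not tested either. Vehicle column 1 of RKO held 361 TPM of VIM, 111 TPM of CAV1 and 739 TPM of TMSB4X, against at most 2.46, 5.69 and 129 TPM in the other 5 columns. Without it the changes were -0.65 for VIM, -1.09 for CAV1, -1.76 for TMSB4X and -1.74 for HIST3H2BB (limma adjusted p = 4.7e-04 at most), and HIST1H3C fell below the minimum of 1 TPM. VIM, CAV1 and HIST1H3C did not pass without doxycycline column 1 (limma adjusted p = 0.34, 0.20 and 0.39) or doxycycline column 2 (0.18, 0.082 and 0.24). After rescaling VIM, CAV1, HIST1H3C and TMSB4X did not pass (limma adjusted p = 0.31, 0.19, 0.35 and 0.058).

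Over the 10551 genes tested in RKO, limma called 1915 changed, 220 higher and 1695 lower, and 3608 had an unadjusted p under 0.05. The median of all tested genes was -0.26, and after rescaling by the median ratio the calls were 2930, 1437 higher and 1493 lower. Small noncoding RNA genes took 71.1%, 67.5% and 71.7% of TPM in the vehicle columns and 78.5%, 70.9% and 75.6% with doxycycline. With these genes removed the median was -0.05, and the calls were 1241 higher and 1610 lower. The shift thus went largely with their share of TPM, and RKO changes are best read against it. Without a minimum TPM limma called 28 genes. Leaving out doxycycline column 1 gave 595 calls and doxycycline column 3 gave 994. The remaining lists were not called in RKO (camera adjusted p of 0.092 or more). Polycomb complexes had 0 higher and 4 lower of 17 (10 lower when adjusted over the list alone), DNA methylation enzymes 0 and 2 of 8 (0 and 3). MYC targets and ribosome biogenesis had 0 and 6 of 28 (0 and 7), nuclear OXPHOS genes 0 and 3 of 29 (0 and 0) and cholesterol synthesis 0 and 2 of 23 (0 and 1). The unfolded protein response had 0 and 4 of 20 (0 and 4), ligand shedding proteins 0 and 2 of 7 (0 and 2). Hypoxia and glycolysis genes had 3 and 7 of 27 (5 and 10), the integrated stress response 4 and 6 of 26 (4 and 8) and interferon-stimulated genes 1 and 2 of 24 (2 and 3). MHC class I genes had 1 and 4 of 17 (1 and 4), NF-kB targets 2 and 2 of 16 (2 and 3). Other natural killer and death receptor ligands had 1 and 2 of 15 (3 and 2), immune checkpoint genes 1 and 1 of 6 (1 and 1) and stemness factors 1 and 2 of 8 (1 and 4). Mesenchymal genes had 1 and 4 of 16 (1 and 10), beside a sum of fibroblast and endothelial markers of 182.8 TPM in vehicle column 1. Fewer than 5 members were tested of the fibroblast and endothelial (0 and 0 of 3), colon (0 and 0 of 2), lung (0 and 0 of 1) and mucin (0 and 1 of 1) lists. No leukocyte or erythroid marker was tested, and the RKO table lists no mitochondrially encoded gene.

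In COLO 201 camera called 9 lists, and 0 with an estimated correlation. Of 29 nuclear genes of oxidative phosphorylation, 27 rose and 0 fell, the same when adjusted over the list alone, with a median of 0.29 (camera adjusted p = 2.8e-04, adjusted p = 0.84 with an estimated correlation). ATP5G1, a subunit of the ATP synthase ring, rose by 0.54 ± 0.05 and COX5A by 0.43 ± 0.04 (limma adjusted p = 1.5e-06 at most). After rescaling 16 of the 29 were higher. Of 19 MHC class I genes, 14 rose and 2 fell, the same when adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.041, adjusted p = 0.63 with an estimated correlation). HLA-B rose from 38.2 ± 2.82 to 87.3 ± 0.820 TPM (1.17 ± 0.05, limma adjusted p = 4.3e-09), the immunoproteasome subunit PSMB9 by 1.14 ± 0.05 and the peptide transporter TAP1 by 0.62 ± 0.05. The MHC call was lost without vehicle column 2 (camera adjusted p = 0.061) or doxycycline column 3 (0.063).

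Of 20 genes of the unfolded protein response in COLO 201, 0 rose and 12 fell, the same when adjusted over the list alone, with a median of -0.12 (camera adjusted p = 2.0e-06, adjusted p = 0.37 with an estimated correlation). The chaperone HSP90B1 fell by 0.49 ± 0.04, the disulfide isomerase PDIA4 by 0.48 ± 0.04 and SEL1L, of the degradation complex, by 0.63 ± 0.06 (limma adjusted p = 1.3e-06 at most). Of 7 proteins linked to shedding of NKG2D ligands, 0 rose and 4 fell, the same when adjusted over the list alone (PDIA4, HSPA5 -0.25, ADAM10 -0.20 and PDIA6 -0.11), with camera adjusted p = 0.017 and adjusted p = 0.66 with an estimated correlation. Of 26 genes of the integrated stress response, 7 rose and 12 fell, the same when adjusted over the list alone (camera adjusted p = 8.5e-04, adjusted p = 0.42 with an estimated correlation). WARS, the tryptophanyl-tRNA synthetase, fell by 1.51 ± 0.04 and holds the 7-base word in its 3′ UTR. Of the 12 that fell, 1 holds the word, against 1.12 for tested genes of like 3′ UTR length. DDIT4 and CHAC1 fell by 0.98 ± 0.07 and 0.78 ± 0.06, while GDF15 rose by 1.08 ± 0.05. Of 35 interferon-stimulated genes, 10 rose and 13 fell, the same when adjusted over the list alone (camera adjusted p = 0.0037, adjusted p = 0.66 with an estimated correlation), with ISG15 at 0.81 ± 0.06 and DDX60 at -1.04 ± 0.08.

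Of 5 mucins tested in COLO 201, 0 rose and 4 fell, the same when adjusted over the list alone: MUC1, the gel-forming MUC5B (-1.003 ± 0.06), MUC13 (-0.57 ± 0.05) and MUC20 (-0.27 ± 0.06), with camera adjusted p = 9.8e-05 and adjusted p = 0.37 with an estimated correlation. The list holds MUC1, the target of the hairpin, and without it 4 mucins remained, fewer than the 5 needed for camera, so the call says nothing of mucins as a group. Of 9 markers of colon epithelium, 2 rose and 5 fell, the same when adjusted over the list alone (camera adjusted p = 0.0051, adjusted p = 0.37 with an estimated correlation, and 0.070 after rescaling). PHGR1 fell from 1111 ± 72.6 to 430.2 ± 25.1 TPM (-1.37 ± 0.05), the lectin LGALS4 by 1.40 ± 0.05 and the antigen GPA33 by 1.25 ± 0.07, and the cadherin CDH17 rose by 1.28 ± 0.08. Of 12 mitochondrially encoded genes, 0 rose and 3 fell, 1 when adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.93 with an estimated correlation). That call was lost without vehicle column 1 (camera adjusted p = 0.18), vehicle column 3 (0.051) or doxycycline column 3 (0.055) and after rescaling (0.15). LYZ, the lysozyme gene, fell from 1219 ± 2.10 to 610.4 ± 16.5 TPM (-0.997 ± 0.04). Of 3 leukocyte and erythroid markers tested, 1 rose and 2 fell.

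The genes that rose most in COLO 201 were KCNJ10 (3.37 ± 0.06), an inwardly rectifying potassium channel that went from 1.22 ± 0.00966 to 22.03 ± 1.32 TPM, and FN1 (2.69 ± 0.05), the fibronectin gene, which went from 24.4 ± 1.29 to 162 ± 8.92 TPM. They were followed by DAAM2 (2.58 ± 0.07), PIR (2.46 ± 0.06), SERPINI1 (2.35 ± 0.05), KCNJ9 (2.30 ± 0.08), a second potassium channel beside KCNJ10 on chromosome 1, the chloride transporter SLC26A9 (2.24 ± 0.07) and the glutathione transferase GSTA4 (2.19 ± 0.06). The genes that fell most were SLITRK5 (-2.49 ± 0.08), MUC1, the alpha-globin HBA2 (-2.33 ± 0.17), the neuropeptide S receptor NPSR1 (-2.21 ± 0.06). Next were SDPR (-2.04 ± 0.07), the chemokine receptor CXCR1 (-2.02 ± 0.09), the cytokine IL18 (-2.02 ± 0.07) and GLCE (-2.01 ± 0.06), whose 3′ UTR holds the 7-base word. All 16 had limma adjusted p of 2.9e-07 or less. HBA2 has a near-identical paralog, so its value is uncertain.

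Over the 11566 genes tested in COLO 201, limma called 7052 changed, 5312 higher and 1740 lower, with 7452 at an unadjusted p under 0.05. The median of all genes was 0.12, and after rescaling the calls were 6618, 3302 higher and 3316 lower. Removal of mitochondrially encoded genes gave 4096 higher and 2360 lower. The remaining lists were not called (camera adjusted p of 0.095 or more). Cell cycle genes had 29 higher and 2 lower of 42, and 10 and 6 after rescaling. Hypoxia and glycolysis had 16 and 5 of 28, MYC targets and ribosome biogenesis 15 and 3 of 28, p53 targets 12 and 6 of 24, cholesterol synthesis 11 and 5 of 24 and NF-kB targets 10 and 4 of 21. Polycomb complexes had 9 and 1 of 18, SWI/SNF complexes 9 and 5 of 17, and DNA methylation enzymes 3 and 1 of 8. Epithelial junction genes had 7 and 7 of 23, stemness factors 6 and 3 of 12 and mesenchymal genes 4 and 2 of 7, among them TGFBI (0.78 ± 0.04) and AXL (-1.12 ± 0.07). Other natural killer and death receptor ligands had 5 and 3 of 12, with FAS, the death receptor, at 0.93 ± 0.08 and PVRL2 at -0.62 ± 0.04. Immune checkpoint genes had 3 and 4 of 9, with NT5E at -0.83 ± 0.05, and lung markers 1 and 1 of 3. Adjusted over the list alone the counts were the same, except for 6 SWI/SNF genes and 6 cholesterol genes lower. No fibroblast or endothelial marker was tested.

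In H1975, interferon-stimulated genes fell. Of 41 tested, 0 rose and 38 fell, 39 when adjusted over the list alone, with a median of -1.05 (camera adjusted p = 9.6e-40, adjusted p = 0.12 with an estimated correlation). IFI6, an interferon-induced mitochondrial protein, fell from 1278 ± 20.4 to 139.8 ± 16.4 TPM (-3.19 ± 0.08, limma adjusted p = 5.9e-12). IFI27 fell from 1214 ± 74.2 to 308 ± 26.8 TPM (-1.98 ± 0.07, limma adjusted p = 2.6e-10), the antiviral GTPase MX1 by 2.30 ± 0.07 (limma adjusted p = 7.2e-11) and IFIT1 by 2.14 ± 0.08 (limma adjusted p = 1.7e-10). XAF1 (-2.64 ± 0.08), OAS1 (-1.79 ± 0.07), which makes the activator of RNase L, and IRF9 (-1.53 ± 0.07), a subunit of the factor that acts downstream of the interferon receptor, also fell. The 3 that did not pass were ISG20 (0.09 ± 0.08), IFIT5 (-0.21 ± 0.09) and USP18 (-0.05 ± 0.08). After rescaling 39 were lower. MHC class I genes had 2 higher and 5 lower of 19 (2 and 4 when adjusted over the list alone, camera adjusted p = 0.22), with the peptidase ERAP1 at -0.48 ± 0.08.

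Beside the interferon-stimulated genes, camera called 5 lists in H1975, and 0 with an estimated correlation. Of 14 mesenchymal genes, 1 rose and 9 fell, the same when adjusted over the list alone, with a median of -0.24 (camera adjusted p = 1.6e-04, adjusted p = 0.69 with an estimated correlation). TGFBI, an extracellular matrix protein, fell from 1069 ± 29.4 to 449 ± 35.2 TPM (-1.25 ± 0.07), the matrix protein SPARC by 0.64 ± 0.07 and COL6A2 by 0.55 ± 0.09 (limma adjusted p = 2.7e-04 at most), while ITGA5 rose by 0.34 ± 0.07. The collagen genes COL1A1 (-1.55 ± 0.08) and COL1A2 (-0.60 ± 0.08) of the fibroblast and endothelial list fell too, the 2 of its members tested. Of 31 hypoxia and glycolysis genes, 4 rose and 15 fell, 16 when adjusted over the list alone, with a median of -0.18 (camera adjusted p = 2.0e-04, adjusted p = 0.78 with an estimated correlation). PGAM1 (-1.11 ± 0.06) and LDHA (-0.84 ± 0.06), glycolytic enzymes whose 3′ UTRs hold the 7-base word, and the carbonic anhydrase CA9 (-0.82 ± 0.09) fell. Of the 15 that fell, 2 hold the word, against 1.13 for tested genes of like 3′ UTR length. Of 23 cholesterol synthesis genes, 12 rose and 0 fell, the same when adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.0030, adjusted p = 0.78 with an estimated correlation), among them IDI1 (0.75 ± 0.09), SQLE (0.44 ± 0.07) and INSIG1 (0.39 ± 0.07).

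Of 6 lung epithelial markers in H1975, 1 rose and 5 fell, the same when adjusted over the list alone, with a median of -0.48 (camera adjusted p = 0.0048, adjusted p = 0.78 with an estimated correlation). The aspartic protease NAPSA fell by 1.18 ± 0.13, the lineage factor NKX2-1 by 0.55 ± 0.08 and KRT7 by 0.41 ± 0.07, and FOXA2 rose by 0.52 ± 0.07. Of 13 mitochondrially encoded genes, 0 rose and 6 fell, the same when adjusted over the list alone, with a median of -0.22 (camera adjusted p = 0.0011, adjusted p = 0.78 with an estimated correlation), among them MT-CYB (-0.53 ± 0.07) and MT-ND3 (-0.55 ± 0.09). The immune checkpoint ligands CD274 (0.66 ± 0.08) and PDCD1LG2 (0.70 ± 0.11) rose, and 3 of 7 checkpoint genes rose and 0 fell, the same when adjusted over the list alone (camera adjusted p = 0.39).

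The genes that rose most in H1975 were AGXT (2.57 ± 0.09), the peroxisomal alanine-glyoxylate aminotransferase, which went from 2.59 ± 0.197 to 20.4 ± 1.86 TPM. Next came the B cell receptor component CD79A (1.96 ± 0.12), the proton pump subunit ATP6V0D2 (1.76 ± 0.08), SPINK1 (1.63 ± 0.09), MACC1 (1.47 ± 0.09), IL1RL1 (1.46 ± 0.08), a receptor of interleukin-33, ARL14EPL (1.45 ± 0.10) and C2ORF54 (1.42 ± 0.09). All 8 had limma adjusted p of 1.2e-07 or less. Beside MUC1 and 5 interferon-stimulated genes, the genes that fell most were MTRNR2L12 (-3.31 ± 0.98, limma adjusted p = 0.017) and MTRNR2L8 (-2.69 ± 0.87, limma adjusted p = 0.025). Both are near-identical nuclear copies of mitochondrial ribosomal RNA, so their values are uncertain, and without vehicle column 1 neither passed (limma adjusted p = 0.064 and 0.075).

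Over the 12359 genes tested in H1975, limma called 4759 changed, 2959 higher and 1800 lower, with 5957 at an unadjusted p under 0.05. The median of all genes was 0.06, the calls after rescaling were 4737, 2281 higher and 2456 lower, and without vehicle column 1 they were 3075. Removal of mitochondrially encoded genes gave 2227 higher and 2407 lower. The remaining lists were not called (camera adjusted p of 0.16 or more). Genes of p53 had 10 higher and 2 lower of 24 (12 and 2 when adjusted over the list alone), nuclear OXPHOS 10 and 0 of 29 (10 and 0), MYC targets and ribosome biogenesis 10 and 1 of 28 (12 and 2). The integrated stress response had 8 and 7 of 29 (8 and 8), epithelial junctions 7 and 2 of 24 (7 and 2) and the cell cycle 7 and 6 of 42 (7 and 5). NF-kB targets had 6 and 6 of 22 (6 and 6), with IL8 at -0.61 ± 0.08, the unfolded protein response 5 and 1 of 20 (5 and 0). Polycomb complexes had 3 and 2 of 18 (2 and 0), SWI/SNF complexes 2 and 3 of 17 (2 and 3) and stemness factors 3 and 1 of 9 (3 and 1), with MYC at 0.61 ± 0.07. Other natural killer and death receptor ligands had 3 and 1 of 14 (2 and 1), with TNFRSF10A at 0.48 ± 0.07. DNA methylation enzymes had 0 and 2 of 8 (0 and 2), with TET1 at -0.71 ± 0.09, and ligand shedding proteins 1 and 0 of 7 (0 and 0). Fewer than 5 members were tested of the colon (1 and 0 of 1), mucin (0 and 1 of 2) and leukocyte and erythroid (0 and 1 of 2) lists.

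**Figure D2:**
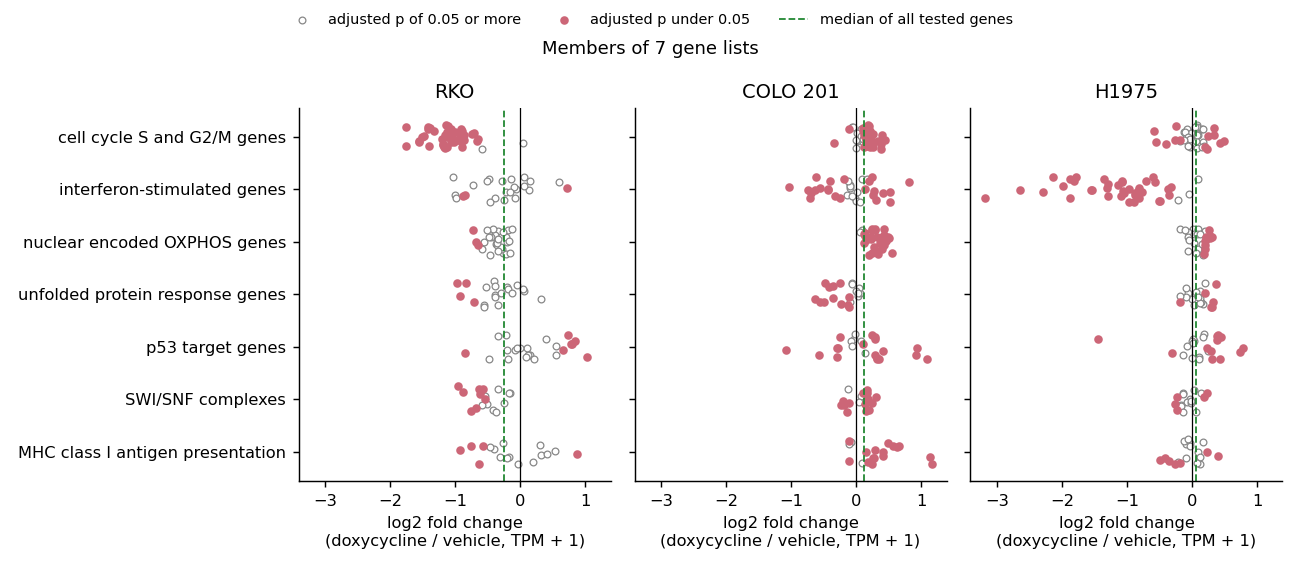
Log2 fold change (doxycycline over vehicle, TPM + 1) of each tested member of 7 gene lists in RKO, COLO 201 and H1975, with members at an adjusted p under 0.05 in pink and the median of all tested genes as a dashed line. In RKO 40 of 42 cell cycle genes were lower, in COLO 201 27 of 29 nuclear OXPHOS genes were higher, 16 after rescaling, and in H1975 38 of 41 interferon-stimulated genes were lower.

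The response differed between lines when the difference itself was tested in a joint limma fit over 12206 genes. RKO and COLO 201 differed at 5466 genes, RKO and H1975 at 4562 and COLO 201 and H1975 at 1814. The change of MICA was larger in COLO 201 than in H1975 by 0.74 ± 0.12 (limma adjusted p = 4.6e-04), that of MICB by 0.69 ± 0.12 (limma adjusted p = 0.0010) and that of RAB27A by 0.53 ± 0.12 (limma adjusted p = 0.0054). Against RKO the change of MICA was larger in COLO 201 by 1.11 (limma adjusted p = 7.2e-06) and in H1975 by 0.37 (limma adjusted p = 0.027). After rescaling the first of these was 0.83 (limma adjusted p = 2.5e-06) and the second was 0.15 and did not pass (limma adjusted p = 0.18). In RKO MICA stood at 0.992 to 1.53 TPM, where the pseudocount holds down the log2 change. Its change there was 0.16 with a pseudocount of 0.1 and 0.036 with 5. The differences from RKO thus do not rank the lines by the size of the rise. For MUC1 no difference passed the test with all columns (limma adjusted p = 0.54, 0.090 and 0.39), where vehicle column 1 of RKO entered the shared spread (SE 0.71 for each pair). Without that column all 3 passed. They were 1.52 for RKO minus COLO 201 (limma adjusted p = 2.2e-08), 2.55 for RKO minus H1975 (5.1e-12) and 1.03 for COLO 201 minus H1975 (3.4e-06). The pseudocount holds down the log2 change where MUC1 is near 1 TPM, as in RKO and in COLO 201 with doxycycline, so these differences do not rank the lines by the depth of the fall. The change of cell cycle genes was lower in RKO than in COLO 201 by a median of 1.31 (camera adjusted p = 7.3e-14, adjusted p = 0.48 with an estimated correlation). That of interferon-stimulated genes was lower in H1975 than in COLO 201 by a median of 0.92 (camera adjusted p = 2.8e-14, adjusted p = 0.25 with an estimated correlation). These medians include the shifts of all tested genes, which were -0.26 in RKO, 0.12 in COLO 201 and 0.06 in H1975. The count for COLO 201 and H1975 was 3200 without RKO vehicle column 1, whose values entered the shared spread, and 3587 after rescaling.

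Genes called in more than 1 line overlapped. RKO and COLO 201 shared 392 lower genes against 217 for independent lists (one-sided Fisher's exact p = 2.7e-39), RKO and H1975 332 against 183 (p = 4.1e-33) and COLO 201 and H1975 398 against 184 (p = 7.7e-61). The shared higher genes, by the same Fisher's exact test, were 102 against 76.2 (p = 2.8e-05), 103 against 46.9 (p = 8.6e-19) and 1514 against 1250.1 (p = 4.2e-32). Genes are not independent replicates, so these p-values are too small. In opposite directions, the overlaps lay below those of independent lists, with 20 and 552 genes for RKO and COLO 201, 18 and 218 for RKO and H1975 and 444 and 232 for COLO 201 and H1975. Of 9402 genes tested in every line, 156 fell in all 3, against 22.3 for independent lists, and 54 rose in all 3, against 19.1.

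Beside MUC1, the genes that fell furthest in every line were WARS (-1.74, -1.51 and -1.84 in RKO, COLO 201 and H1975), the kinase MAPKAPK2 (-1.15, -1.05 and -1.25), the ubiquitin-conjugating enzyme UBE2Q2 (-1.33, -1.28 and -1.03), the proteasome subunit PSMB5 (-1.62, -1.13 and -1.002). The others were the ADP-dependent glucokinase ADPGK (-1.11, -1.002 and -0.92), FAM49B (-1.39, -1.18 and -0.91) and the carbonic anhydrase CA13 (-0.91, -0.89 and -1.01), all with limma adjusted p of 0.0018 or less. The genes that rose furthest in every line were GDF15 (0.84, 1.08 and 0.78), the lysosomal glycoprotein CD68 (1.21, 0.70 and 0.92), and the kinase DYRK3 (0.86, 0.74 and 0.70). They were followed by C9ORF72 (1.38, 0.66 and 0.90), the autophagy protein WIPI1 (0.85, 0.84 and 0.65), NIPAL3 (1.19, 0.65 and 0.55), the integrin ITGA2 (0.80, 0.55 and 0.68) and the glutaminase GLS2 (0.68, 0.94 and 0.52), all with limma adjusted p of 0.030 or less. In RKO, ITGA2 did not pass without vehicle column 1 (limma adjusted p = 0.059), doxycycline column 1 (0.060) or doxycycline column 2 (0.073), and GLS2 did not pass without any 1 of the 3 doxycycline columns (0.096, 0.11 and 0.16).

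Of the 156 genes lower in every line, 152 had an annotated 3′ UTR, and 86 of these (56.6%) held the 7-base word ATCAGTA in it, against 23.6 (15.5%) for genes of like 3′ UTR length. WARS, MAPKAPK2, UBE2Q2, PSMB5, ADPGK, FAM49B and CA13 each held it. The word was found in these genes, so they were left out of the counts of other genes, which were not matched for length. In RKO the share called lower was 14.3% of 8204 other genes without the word, 22.9% of 686 with it and no adenine after it, and 27.5% of 291 with an adenine after it. In COLO 201 the shares were 10.2%, 23.8% and 34.7%. In H1975 they were 8.79%, 7.73% and 11.7%, and 8.91% of all 977 genes with the word. The word occurs once in the MUC1 mRNA, at GRCh38 chromosome 1, 155187772 to 155187778 on the minus strand, in the coding sequence of exon 8 of 11.

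**Figure D3:**
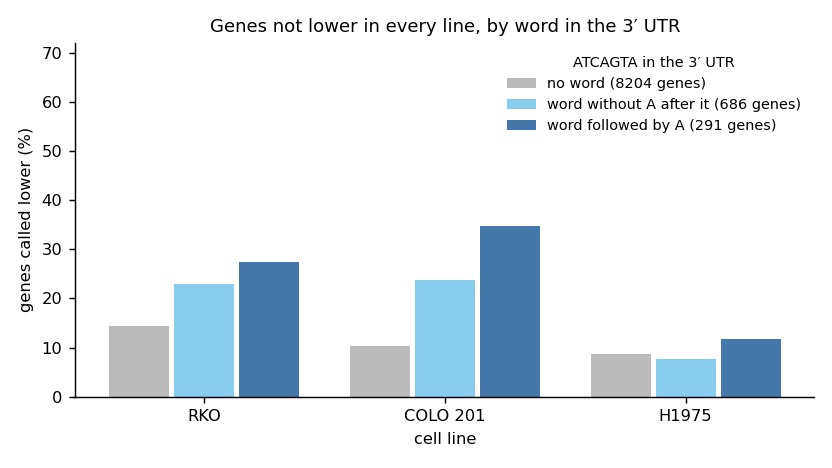
Percent of genes called lower by limma (vertical axis) in RKO, COLO 201 and H1975 among 8204 genes without the word ATCAGTA in the 3′ UTR (grey), 686 with the word and no adenine after it (light blue) and 291 with the word followed by an adenine (blue). The genes lower in every line, in which the word was found, are left out. The shares without the word and with the word and an adenine were 14.3% and 27.5% in RKO, 10.2% and 34.7% in COLO 201 and 8.79% and 11.7% in H1975.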

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

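The tests of a mesenchymal source, of H1975 as the only source, of another line in place of RKO and of other splits were chosen after the results had been seen, and those of COLO 201 and H1975 cells as sources before. RKO vehicle column 1 lay far from the other 5 RKO columns in 3 of 16 RKO groups tested with Dixon's test, where chance alone gives about 1 in 20, or 0.8 (over the 3 lines 3 of 50, against 2.5). It held 16935 genes above 0 (others 14935 to 15216), 182.8 TPM of fibroblast and endothelial markers (others 0.0042 to 0.0199) and 15.2 TPM of MUC1 (others 0.105 to 1.24).

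In that column the collagen genes COL1A1, COL1A2 and COL3A1 stood at 54.6, 84.8 and 41.2 TPM, with THY1 at 56.2 and TWIST1 at 26.97 TPM, against at most 0.00856 TPM in the other RKO columns, while PDGFRB (0.0157), DCN (0.994), LUM (1.19), PECAM1 (0.0226), VWF (0) and CDH5 (0) were low. A mesenchymal cell type as the source was not decided, since the collagens (lowest 41.2 TPM) belong to the list that set the column apart, but COLO 201 cells as the source do not go with the data, since 17.3% of 127 genes abundant in COLO 201 and near 0 in RKO were above 0.5 TPM in the column. H1975 cells as the only source do not go with the data either, since of 77 genes found at 10 TPM or more in this column alone among the RKO columns 45.5% lay above the highest H1975 column, and 70.1% once the columns had the same median over shared genes (the 14.3% near 0 in every H1975 column lay between its bounds and decided nothing), while a part from H1975 cells beside another source cannot be told apart, as the share for H1975 was 60.7% of 107 genes, between the bounds set. Against another line in place of RKO, 0 of 2055 genes at 20 TPM or more in the other RKO vehicle columns fell under 0.3 of their mean (median ratio 0.904), against 11.4% and 10.1% of these genes in COLO 201 and H1975 brought to the same median. So the RKO profile was kept and 551 genes over 1 TPM came on top, which RNA from other cells or RKO cells in another state could both give, and no biological explanation was tested.

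Effects differed between lines, by a test of the difference in limma, at 5466 genes for RKO and COLO 201, 4562 for RKO and H1975 and 1814 for COLO 201 and H1975. The fit held genes under the minimum TPM in 1 or more lines. Of 100 splits of the columns within lines, the real one included, 1 gave as many for RKO and COLO 201 (highest other 3275) and 1 for RKO and H1975 (highest other 3176). For COLO 201 and H1975 2 did, since another split called 2318, more than the real 1814. Splits that mix the arms put the doxycycline effect into the spread and so tend to call few genes. The rank of the real split therefore says little about chance.

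Study genes with a different effect in RKO than in COLO 201, as RKO minus COLO 201 with limma adjusted p, were MICA -1.11 (7.2e-06), MICB -0.98 (2.6e-05), RAB27A -0.59 (0.0010), PDIA6 -0.42 (0.045), DNMT1 -1.17 (1.4e-05), DNMT3B -0.41 (0.014) and EZH2 -0.65 (0.0062). As RKO minus H1975 they were MICA -0.37 (0.027), PDIA6 -0.73 (0.0031), DNMT1 -1.07 (5.9e-05), DNMT3B -0.53 (0.0047) and EZH2 -0.65 (0.0086). As COLO 201 minus H1975 they were MICA 0.74 (4.6e-04), MICB 0.69 (0.0010), RAB27A 0.53 (0.0054) and DNMT3A 0.43 (0.033). MICA, MICB, RAB27A and DNMT3B reached at most 1.53, 1.46, 2.38 and 1.88 TPM in RKO. There the pseudocount holds down the log2 change, so their differences from RKO do not compare fold changes. The medians of all genes differ between lines, and after rescaling 3 of these 16 did not pass. For RKO and COLO 201 PDIA6 was -0.0066 (limma adjusted p = 0.94) and DNMT3B -0.16 (0.26), and for RKO and H1975 MICA was -0.15 (0.18). Others passed but shrank by over 1.5 times: for RKO and COLO 201 DNMT1 was -0.77, RAB27A -0.28 and EZH2 -0.25, and for RKO and H1975 PDIA6 was -0.38, EZH2 -0.31 and DNMT3B -0.31.

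Among the 12206 genes of the joint fit, genes called in opposite directions numbered 572 for RKO and COLO 201, 236 for RKO and H1975 and 667 for COLO 201 and H1975, and of these 569, 234 and 477 had a difference called by limma. PALM3 fell in RKO and rose in COLO 201 (difference -2.35), as did TIMELESS (-1.73), and ZNF165 rose in RKO and fell in COLO 201 (2.14), with limma adjusted p of 8.5e-08 or less. The kinetochore gene DSN1 (-1.71), the origin recognition gene ORC1 (-1.57) and E2F2 (-1.51) fell in RKO and rose in H1975, with limma adjusted p of 1.0e-06 or less. PIR (2.94) and TMT1A (2.34) rose in COLO 201 and fell in H1975, and MAB21L4 (-2.28) did the reverse, with limma adjusted p of 5.4e-10 or less.

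Lists with a different effect by camera in the joint limma fit, as RKO minus COLO 201 in the median, were SWI/SNF complexes -0.55, epithelial junctions 0.16, cell cycle -1.31, p53 targets 0.0305, nuclear OXPHOS -0.64, mucins 0.55 and colon markers 0.45, with interferon-stimulated genes -0.19 and the integrated stress response -0.21, where camera, which ranks against all other genes, pointed up. As RKO minus H1975 they were interferon-stimulated genes 0.64, MHC class I 0.0192, epithelial junctions 0.0535, cell cycle -1.12, MYC targets -0.47, nuclear OXPHOS -0.47, mucins 0.15 and p53 targets -0.0278, where camera pointed up. As COLO 201 minus H1975 they were interferon-stimulated genes 0.92, MHC class I 0.33, epithelial junctions -0.0735, the unfolded protein response -0.26, cholesterol synthesis -0.13, hypoxia and glycolysis 0.31, mucins -0.24 and colon markers -0.83. The adjusted p ran from 1.0e-26 to 0.043. With an estimated correlation mucins (0.0093) and colon markers (0.0013) stayed called for RKO and COLO 201, and colon markers (0.013) for COLO 201 and H1975. Only 2 colon markers reached the minimum in RKO and 1 in H1975, against 9 in COLO 201, so these calls mostly restate the change in COLO 201. Other lists in the joint fit also hold genes under the minimum in a line, as with 41 interferon-stimulated genes against 24 tested in RKO. The mucin list holds MUC1, whose own difference is its median for RKO and COLO 201, and without MUC1 4 mucins remained, too few for camera, so the mucin calls say nothing of other mucins.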

How the results depend on the processing

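The alternatives with small noncoding RNA genes removed, with RKO vehicle column 1 out and rescaled, and the rescaled lists and between-line counts and genes were chosen after results had been seen. The removal of mitochondrially encoded genes was not possible in RKO, whose table lists none. For MUC1, MICA, MICB and RAB27A in COLO 201, and for MUC1 and MICA in H1975, every alternative kept the direction and the call. Leaving out a column leaves an arm of 2. Where no reason is given, the cause was not tested.

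RKO gene counts were 28 without a minimum TPM, 2930 rescaled, 6053 with vehicle column 1 out and rescaled, 403 at 2-fold, and 595 and 994 without doxycycline column 1 or 3, up to 2410 without single columns. The RKO count at 2-fold, 47 higher and 356 lower, was 237 rescaled, 120 higher and 117 lower. It ran from 251 without doxycycline column 1 to 796 without vehicle column 3. At 2-fold COLO 201 had 194 and H1975 113, and H1975 had 3075 without vehicle column 1, up to 5206.

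In RKO (limma adjusted p in brackets), MUC1 was -3.60 (4.6e-09) with pseudocount 0.1, -0.83 (0.099) with pseudocount 5, -1.88 (0.26) without a minimum, -1.77 (0.15) rescaled, -2.771 (0.081) with small noncoding RNA removed and -2.40 to -1.859 without single columns, losing the call without doxycycline column 1 (-1.861, 0.17) or 2 (-1.859, 0.082). With vehicle column 1 out and rescaled, MICA was 0.29 (9.1e-04), MICB 0.26 (0.0020), RAB27A 0.23 (0.0044), PDIA6 -0.27 (0.0014), DNMT3A -0.19 (0.021) and EZH2 -0.30 (0.0013). Rescaled, RAB27A was 0.27 (0.042), PDIA6 -0.24 (0.033) and EZH2 -0.27 (0.038). With small noncoding RNA removed, RAB27A was 0.34 (0.040), PDIA6 -0.27 (0.034) and EZH2 -0.30 (0.046). EZH2 was -0.55 (0.042) at a minimum of 5 TPM, and DNMT1 -1.06 (0.053) without a minimum. Without single columns MICB reached -0.024 to -0.0066, RAB27A -0.018, PDIA6 -0.69 to -0.402 and EZH2 -0.72 to -0.401.

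With the column number as a block in limma, RKO MUC1 was -1.88 (0.11), PDIA6 -0.53 (0.038) and EZH2 -0.55 (0.036), and H1975 PDIA6 was 0.20 (0.081). The block changed no other call of a study gene.

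In COLO 201 (limma adjusted p in brackets), rescaling turned DNMT1 to -0.0066, DNMT3B to -0.051 and EZH2 to -0.015. Removal of mitochondrially encoded genes turned DNMT3B to -0.0076 and left DNMT1 at 0.0504 (0.31) and EZH2 at 0.04 (0.42). Without the trend PDIA6 was -0.11 (0.070), DNMT1 0.12 (0.063) and EZH2 0.11 (0.070). Without single columns DNMT1 was 0.086 to 0.142, DNMT3B -0.023 to 0.0922, EZH2 0.087 to 0.135 and PDIA6 -0.141 to -0.085. In H1975 DNMT1 turned to -0.040 rescaled, -0.033 with mitochondrially encoded genes removed and ran from -0.018 to 0.0483 without single columns. PDIA6 was 0.20 (0.055) without a minimum, 0.20 (0.055) without the trend, 0.14 (0.062) with mitochondrially encoded genes removed and 0.148 to 0.236 without single columns, and MICB was 0.30 (0.052) without vehicle column 1.

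With an estimated correlation camera called 0 lists in RKO, 0 in COLO 201 and 0 in H1975, and fry called 0 in RKO, 20 in COLO 201 and 7 in H1975. COLO 201 and H1975 differed at 1058 genes with pseudocount 0.1, 1002 at a minimum of 5 TPM, where fewer genes were tested, 3587 rescaled and 3200 without RKO vehicle column 1. Between lines, in limma (adjusted p in brackets), rescaling turned DNMT3A for RKO minus COLO 201 to 0.070 (0.67), and to 0.179 (0.091) with RKO vehicle column 1 also out. It turned RAB27A for RKO minus H1975 to 0.183 (0.027) and EZH2 for COLO 201 minus H1975 to -0.0578 (0.58), and PDIA6 for COLO 201 minus H1975 came to -0.375 (1.6e-04) and DNMT3A for RKO minus H1975 to 0.436 (0.0094). At 2-fold, RKO and COLO 201 shared 0 higher and 15 lower genes, with 1 higher then lower and 3 lower then higher, RKO and H1975 shared 4 and 9, with 0 and 0, and COLO 201 and H1975 shared 0 and 8, with 1 and 1.

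Of the other named genes, 698 of 885 values in RKO kept their call under other settings and 463 of 602 with a column left out. In COLO 201 these were 1035 of 1044 and 786 of 796, and in H1975 957 of 985 and 703 of 748. None turned.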

Other observations

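Of the tests here, only the excess of 3′ UTR words with a match in the MUC1 mRNA was chosen before the result was seen. Histone genes fell in RKO: of 55 tested, 0 were higher and 49 lower in limma, with a median log2 change of -1.61, and after rescaling 0 and 46. In COLO 201 28 of 64 were higher and 9 lower, 7 and 12 after rescaling, and in H1975 4 of 63 were higher and 21 lower. This set was formed after values had been seen, and histone genes share reads. Histone genes took 0.496% to 2.11% of TPM in RKO, 14.2% to 16.7% in COLO 201 and 1.14% to 1.27% in H1975. The libraries held polyadenylated RNA, and how fully they capture histone messages was not tested. Of the neighbouring genes lower in RKO by at least 2-fold, 11 histone genes stood in a row at chromosome 6, 26103876 to 26217483, and in H1975 OAS1, OAS3 and OAS2 did so at chromosome 12.

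The 156 genes lower in every line held the word ATCAGTA in the 3′ UTR more often than genes of like length (86 of 152 against 23.6). The Bonferroni p, from a normal approximation of the count over genes, was 8.36e-47, and the word also stands in the MUC1 mRNA, as 11.96% of tested words do. Its z was 15.0, above the highest of 100 random sets of like length (5.49, which 1 of 100 further random sets passed), and genes with the word that were not lower in every line also had lower means in 3 lines, by 0.12, 0.12 and 0.03 (length-matched permutation p = 1e-05, 1e-05 and 9e-05, where 1e-05 is the smallest possible), though in H1975 8.91% of them were called lower against 8.79% of genes without the word. Scaling of the tables as the whole cause does not go with the 77.6% of these genes still lower in every line after rescaling. Seed matches of the induced hairpin fit, which could make part of the shared decrease independent of MUC1, but the hairpin sequence was not given, and neither a control hairpin nor a second hairpin was at hand.

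In COLO 201 the neighbours KCNJ10 (3.37), PIGM (1.12), KCNJ9 (2.30) and IGSF8 (1.98) rose together at chromosome 1, 159998651 to 160098943. Chance order of the genes does not go with the run, since 0 of 1000 shuffles gave one as long and the longest had 3 genes. Reads shared between KCNJ10 and KCNJ9 do not explain it, since the lower of the changes of PIGM and IGSF8 was 1.12. PIGM lies within the span of KCNJ10 on the same strand, so transcription running through it stays open for PIGM. A doxycycline-responsive vector inserted nearby could also give the run and cannot be told apart, since in the other lines, where PIGM and IGSF8 were tested, 0 of 4 tests were called higher.

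With 6 columns there are 10 splits into 3 and 3, so the share of splits cannot be under 0.05 (the least is 0.1). The real split called 1915 genes in RKO, 7052 in COLO 201 and 4759 in H1975, and in each line it was 1 of 10 splits with as many, with 0 as the highest other in limma. The other splits mix the arms and carry the doxycycline effect in their spread, so these counts of 0 say little about chance. For lists the real numbers were 4 in RKO, reached by 9 of 10 splits (highest other 6), 9 in COLO 201, reached by 1 of 10 (highest other 8), and 6 in H1975, reached by 3 of 10 (highest other 9).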
